A study of Triticum aestivum with 12 samples.

How the data were processed

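Poly-A RNA from field-grown wheat (Triticum aestivum) was sequenced from 12 samples taken at 1 German site in 2021. The labels put 3 libraries in each of 4 groups: leaf and root of first wheat, which is the first wheat crop after a break crop, and leaf and root of the third wheat crop in succession, called third-wheat here. The labels do not say whether the samples of a group came from separate plots or plants, so p-values measure the spread between these samples, which may be partly technical. Groups and library numbers were taken from the sample titles. The third-wheat samples numbered 3 in the titles are numbered 4 in the library names, in leaf and root. The labels' description field marks leaf libraries as control and root libraries as treatment, which follows the organ and not the succession, and it was not used.

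Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was captured on poly-T beads, and directional libraries were made by the dUTP method. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used. The strand setting of the counting and the genome build are not given in the sources used here. The deposited values are FPKM (fragments per kilobase of gene, scaled to sequencing depth) for 266760 gene models, of which 159846 are low-confidence models, marked LC in their identifiers. A total of 149807 models are listed at 0 in all 12 libraries. Gene names are the Swiss-Prot or Pfam texts that the deposited table pairs with each identifier, and coordinates are given as in that table. No identifier matched the reference gene table used here (0 matches). Wheat carries 3 related subgenomes (A, B and D), so near-identical copies of a gene can share reads and the value of a single copy is uncertain. Overlapping and antisense genes are uncertain for the same reason.

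Sequencing depth was recovered from the steps of the FPKM values. With the listed gene lengths 81.1% of the values above 0 were whole fragments within a tolerance of 0.001, and after finding another length for 17395 genes 100.0% were. Assigned fragments came to 14602566 to 16405500 per library. Within groups, every pair of libraries differed well beyond sampling noise (mean chi-square per gene 7.17 to 19.7), so no library was counted as a duplicate.

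The analysis used log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with an FPKM of at least 1 in at least 3 libraries of a fit were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend and robust options, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with calls at 0.05. The succession effect, third-wheat against first-wheat, was fitted within each organ on 6 libraries. The name stands for the contrast between the crops. The labels do not give plots or sampling times, so a difference in either between first-wheat and third-wheat samples cannot be told apart from succession. The difference between organs in the succession effect (interaction) and root against leaf were fitted on all 12 libraries. The method was tested on data simulated from the real means, with 100 genes changed at each of 2 sizes. It recovered 40% of the 4-fold changes and 2% of the 2-fold changes in root, 56% and 10% in leaf, 26% and 4% for the interaction, and 67% and 32% for root against leaf. No recovered gene had the wrong sign (0 cases). Unchanged genes made up 2 of 44 calls in root, 6 of 72 in leaf, 5 of 35 for the interaction and 3 of 102 for root against leaf. The simulation drew each gene independently, without correlation between genes or libraries that stand apart. For root against leaf it started from no organ difference in the unchanged genes, unlike the data. These rates may therefore differ from those in the real libraries.

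A set of 28 gene lists was fixed as text patterns before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. For each list the number of members called is also given with p-values adjusted over the list alone. A list of chloroplast-encoded genes had no members and was not tested. Some patterns caught unintended genes. In all, 6 entries of the SWEET list are glycoprotein-folding proteins with the alternative name PRIORITY IN SWEET LIFE and 317 entries of the pathogenesis-related list are methionine or cystathionine enzymes. A further 105 entries of the photosynthesis list carry a plastocyanin-like domain found in laccases and phytocyanins, and 82 entries of the cytosolic ribosome list are mitochondrial. The lists as fixed give the main values. Versions without these entries were added from the annotation text, after a first fit had shown counts and gene identifiers. FPKM summed over the SWEET list was compared by an exact two-sided permutation test of the difference of means, which with 3 libraries against 3 cannot give a p under 0.1.

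The rule for named genes was fixed beforehand. For each organ it takes called SWEET members and the 3 SWEET entries with the highest mean FPKM. It adds the 5 called genes of largest change in each direction among annotated genes with at least a 1 log2 change, a mean FPKM of 5 or more in the higher group and no overlap between groups. It also takes up to 3 called members of each list that passed or held at least 3 called genes. For root against leaf it takes 5 SWEET members per direction and the 3 genes of largest fold per direction with a mean FPKM of at least 100. As run, this kept only called genes, and annotated ones for the largest folds. For the interaction it takes the 5 annotated genes of smallest adjusted p and any called SWEET member. Genes named outside the rule are said to be so.

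Alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, upper-quartile scaling, an added fold threshold, a block for the sample number, array weights, 1 fit for all 12 libraries, and leaving out each library. An edgeR quasi-likelihood test was also planned and was not run. Chosen after the data were seen were limma voom on the recovered fragments, lists without unintended entries, fits without libraries that stand apart, list tests for the interaction and for root against leaf, a scan of annotation families, and the tests on circadian clock genes, on reads shared between gene copies and on chloroplast-type genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.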

Results

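Gene expression was measured by RNA sequencing in leaves and roots of first-wheat and third-wheat crops. There were 3 libraries in each of the 4 groups, with 14602566 to 16405500 assigned fragments per library. Libraries of a group correlated at r = 0.945 to 0.976 across genes, libraries of the same organ and the other succession position at 0.938 to 0.966, and libraries of different organs at 0.482 to 0.547. Genes are not independent replicates. The study asked whether growing wheat after wheat changes sugar transporter expression, and whether roots and leaves respond in different ways. The design implies 4 comparisons: root against leaf, third-wheat against first-wheat in each organ, and the difference between the organs in that effect.

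Members of the SWEET family, which moves sugars across membranes, differed in level between roots and leaves. All 10 SWEET13 copies tested were higher in leaf, with a median log2 difference of -2.99, root minus leaf. The 3 most abundant copies in first-wheat roots, named after their values were seen, were those on 6B (TraesCS6B03G1183800, 42.1 ± 13.1 FPKM, SD, n = 3), 6A (TraesCS6A03G0966800, 28.1 ± 3.93) and 6D (TraesCS6D03G0847700, 23.5 ± 7.25). They had 247.9 ± 31.8, 188.5 ± 19.9 and 120.6 ± 11.3 FPKM in first-wheat leaves. Another copy on 6D (TraesCS6D03G0847200) had 59.1 ± 2.61 FPKM (SD, n = 3) in first-wheat leaves and 0.23 ± 0.31 in first-wheat roots. The SWEET1a copy on 3D (TraesCS3D03G0888100) was higher in root, at 19.5 ± 7.42 FPKM in first-wheat roots and 0.09 ± 0.16 in first-wheat leaves.

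SWEET12 copies on 4D and 4A (TraesCS4D03G0457200 and TraesCS4A03G0251100) and a SWEET14 copy on 6B (TraesCS6B03G0033500) were listed at 0 in every leaf library. In first-wheat roots they had 5.75 ± 0.90, 2.44 ± 0.35 and 3.15 ± 1.91 FPKM. SWEET2a on 6D (TraesCS6D03G0308500) had 12.7 ± 2.41 FPKM in first-wheat roots against 2.09 ± 0.71 in leaves. Beside TraesCS6D03G0847200, the rule named as higher in leaf SWEET13 copies on 6A (TraesCS6A03G0966400, log2 difference -4.31) and on 6B (TraesCS6B03G1183300, -4.00; TraesCS6B03G1183600, -3.48; TraesCS6B03G1183500, -5.25). Another 6 transporters higher in leaf, named after their values were seen, were SWEET1a on 1D and 1A (TraesCS1D03G0639100, -3.73, and TraesCS1A03G0674900, -3.65), SWEET1b on 1B (TraesCS1B03G0767200, -2.61) and 3 SWEET3b copies (TraesCS1D03G0300400, -1.71; TraesCS1A03G0325800, -1.28; TraesCS1B03G0405900, -1.20). SWEET1a copies so lay on both sides. SWEET4 copies on 6A and 6D (TraesCS6A03G0600000 and TraesCS6D03G0504200) had 11.7 ± 2.0 and 13.3 ± 1.30 FPKM in first-wheat roots and 15.6 ± 1.43 and 14.1 ± 1.72 in leaves and did not pass the test (limma adjusted p = 0.155 and 0.355). Of the SWEET list, 15 members were higher in root and 21 in leaf, over all genes and when adjusted over the list alone. Without the glycoprotein-folding entries these were 15 and 16. The list had a median log2 difference of -0.39 and a camera adjusted p = 0.0111, in a test chosen after the data were seen, with adjusted p = 0.369 with an estimated correlation. For transporters alone the median was 0.18 and the test direction was lower in root (adjusted p = 0.0835). Of the 28 lists, 20 passed camera for root against leaf, 16 higher in root and 4 in leaf. With an estimated correlation 6 passed: root marker, ethylene and phenylpropanoid and lignin (adjusted p = 0.0325) and peroxidase (0.0480) as higher in root, and photosynthesis (0.0391) and Calvin cycle (0.0480) as higher in leaf.

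Beyond the SWEET list, called and annotated genes with a mean FPKM of at least 100 in the higher organ were ranked by fold. Among them the largest root excess was in a pathogenesis-related protein 1 gene on 2B (TraesCS2B03G1127400), with 980 ± 113 FPKM in first-wheat roots and 0.79 ± 0.19 in leaves. A lipid transfer protein gene on 7A (TraesCS7A03G1094900, log2 difference 8.67) and a quinone dehydrogenase FQR1-like gene on 2A (TraesCS2A03G0256400, 8.61) followed. The largest leaf excess among the ranked genes was in a photosystem II 10 kDa polypeptide gene on 6B (TraesCS6B03G1161500, -10.82). Chlorophyll a-b binding protein genes, which capture light, followed on 1A and 5A (TraesCS1A03G0986900, -10.73, and TraesCS5A03G0843800, -10.52). Of 61389 genes tested with limma, 24111 were higher in root and 15226 in leaf. Quantile normalization, which moved the median log2 difference of all genes from 0.16 to -0.03, gave 20095 and 19778.

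SWEET13, the most abundant SWEET family in these leaves, had lower values in third-wheat leaves. Summed over its 12 copies, SWEET13 was 1024 ± 90.3 FPKM (SD, n = 3) in first-wheat leaves and 707.7 ± 144 in third-wheat leaves, a change of -30.9%. Every third-wheat library (614.7 to 874) lay below every first-wheat library (920.1 to 1083.4). The exact two-sided permutation p = 0.1 is the smallest that 3 libraries against 3 can give, so no such sum can pass 0.05. In roots the SWEET13 sum was 107.9 ± 27.0 FPKM in first-wheat and 122.3 ± 29.4 in third-wheat libraries, which overlapped (exact permutation p = 0.6).

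**Figure D1:**
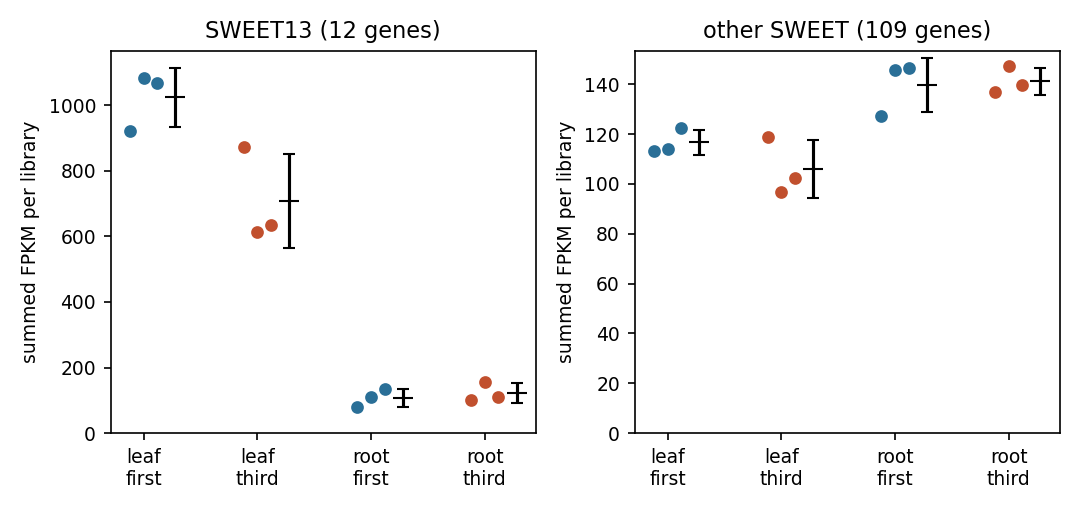
Summed FPKM of the 12 SWEET13 genes (left) and of the 109 other SWEET transporter genes (right) in each library, by organ and by first or third-wheat position; points are libraries (blue for first-wheat, orange for third-wheat), and the bars beside them give the mean and SD of 3 libraries. The 3 third-wheat leaf libraries have SWEET13 sums of 614.7 to 874 FPKM, below the 920.1 to 1083.4 of the first-wheat leaf libraries.

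The other 109 SWEET transporter genes together had 116.7 ± 5.1 and 106.0 ± 11.6 FPKM in leaves (exact permutation p = 0.3) and 139.7 ± 10.9 and 141.2 ± 5.4 in roots (exact p = 0.8). The SWEET list as fixed summed to 1758.2 ± 107 FPKM in first-wheat leaves and 1359 ± 169 in third-wheat leaves (exact permutation p = 0.1). In roots it summed to 387.4 ± 61.4 and 460.4 ± 35.9 (exact p = 0.2). Transporters alone gave 1140.7 ± 93.0 and 813.7 ± 156 in leaves (exact p = 0.1), and 247.6 ± 37.3 and 263.4 ± 34.8 in roots (exact p = 0.6). The root difference of the list as fixed was 73.1 FPKM, and 38.8 without root library 1 of first-wheat, which stands apart from the other root libraries.

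Gene by gene, limma called 0 of the 32 list members tested in leaf over all genes. At an unadjusted p under 0.05 there were 11, all lower in third-wheat leaves, 8 of them when adjusted over the list alone, and voom called 0. The list-alone count was 7 without library 1 of either crop and 0 without library 2 or 3 of either crop. Of the 10 SWEET13 copies tested in leaf, all had log2 fold changes below 0, from -0.75 to -0.31, and 9 had an unadjusted p under 0.05. Without third-wheat library 2 these were 5 copies and 6 list members. The most abundant copy, on 6B at 701819119 to 701821094 (TraesCS6B03G1183800), had 247.9 ± 31.8 and 166.6 ± 38.0 FPKM. Its log2 fold change was -0.58 ± 0.18 (SE), with a limma adjusted p = 0.222. In roots it had 42.1 ± 13.1 and 45.1 ± 9.25 FPKM (log2 fold change 0.13, adjusted p = 0.977). The other entries that abundance put among the named genes were calreticulin-3 genes on 3B and 3D (TraesCS3B03G1065300 and TraesCS3D03G0868700), chaperones of glycoprotein folding and not sugar transporters. Their log2 fold changes were 0.48 and 0.57 in root (adjusted p = 0.524 and 0.293) and -0.23 and -0.18 in leaf (adjusted p = 0.528 and 0.643).

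The leaf SWEET list had a median log2 fold change of -0.22 and a camera adjusted p = 1.09e-05, with adjusted p = 0.536 with an estimated correlation. For transporters alone these were -0.29, 1.87e-05 and adjusted p = 0.533 with an estimated correlation. The root SWEET list had a median of 0.10 and a camera adjusted p = 0.390, and transporters alone had 0.972. In root limma called 0 of 33 members over all genes and 0 when adjusted over the list alone, 6 had an unadjusted p under 0.05, and voom called 0. Of these 6, 3 were calreticulin-3 genes with values above 0 and 3 were transporters, 2 of them below 0, named after their values were seen. SWEET12 on 4D (TraesCS4D03G0457200) had 5.75 ± 0.90 FPKM in first-wheat and 2.62 ± 1.40 in third-wheat roots, SWEET2a on 6A (TraesCS6A03G0354300) 14.8 ± 1.45 and 9.21 ± 5.12, and SWEET13 on 6A (TraesCS6A03G0966400) 5.21 ± 0.64 and 8.02 ± 1.86. Without first-wheat library 1 or third-wheat library 2 there were 3 at an unadjusted p under 0.05, and without third-wheat library 1 there were 2 lower over the list alone.

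Third-wheat roots had higher expression of 56 genes than first-wheat roots. Among them were cinnamoyl-CoA reductase 1 copies on 7A, 7B and 7D, which act in making lignin precursors. The copy on 7A (TraesCS7A03G0349500, 106039037 to 106041027) went from 7.13 ± 0.74 to 34.1 ± 2.87 FPKM (SD, n = 3). Chitinase 4 on 2A (TraesCS2A03G0857500, 594564117 to 594565441), which breaks down chitin, went from 44.5 ± 10.8 to 185.9 ± 26.7. Wheatwin-1 on 3A (TraesCS3A03G1217600), a pathogenesis-related protein, went from 53.1 ± 11.1 to 345.9 ± 155 FPKM, and a thaumatin-like protein gene on 7B (TraesCS7B03G1122500) from 10.99 ± 5.94 to 91.1 ± 34.7. Of 52866 genes tested with limma, 56 were higher in third-wheat roots and 0 lower, with 4429 at an unadjusted p under 0.05. Voom on recovered fragments called 39 higher and 0 lower.

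Among the 56, pathogenesis-related genes were the largest listed group: 9 of 490 tested members were called higher and 0 lower, and 46 higher and 2 lower when adjusted over the list alone. Without methionine and cystathionine enzymes 9 of 329 were called. They included chitinase 4 on 2A (TraesCS2A03G0857500, log2 fold change 2.06 ± 0.21 SE, adjusted p = 0.0329) and a thaumatin-like pathogenesis-related protein 4 gene on 5A (TraesCS5A03G0044200, 1.84 ± 0.18). The glucan endo-1,3-beta-glucosidase GII gene on 3D (TraesCS3D03G1056500, 1.47 ± 0.16) was another, of an enzyme that cuts cell wall glucans. The phenylpropanoid and lignin list had 7 of 386 members called, all higher, and 21 higher and 2 lower when adjusted over the list alone. The 7 were 5 cinnamoyl-CoA reductase 1 genes and 2 laccase-15 genes. The named copies on 7A, 7B (TraesCS7B03G0142900) and 7D (TraesCS7D03G0337500) had log2 fold changes of 2.11 ± 0.16, 1.88 ± 0.17 and 1.54 ± 0.15 with adjusted p = 0.0188, 0.0328 and 0.0329. Without first-wheat libraries 1, 2 and 3 and third-wheat libraries 1, 2 and 3 in turn, called pathogenesis-related members numbered 0, 0, 0, 0, 0 and 10, and 30, 36, 39, 41, 30 and 53 over the list alone. For phenylpropanoid and lignin these were 1, 0, 0, 0, 0 and 9, and 20, 19, 22, 23, 13 and 18. Both lists had an adjusted p = 0.488 with an estimated correlation.

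Single members of other lists also rose in third-wheat roots. The glutathione S-transferase GSTF1 gene on 1A (TraesCS1A03G0193000), of a family of detoxifying enzymes, went from 7.96 ± 0.82 to 24.2 ± 4.83 FPKM. High-affinity nitrate transporter 2.1 on 6D (TraesCS6D03G0074700) went from 0.55 ± 0.09 to 5.55 ± 1.75, and peroxidase 1 on 7A (TraesCS7A03G0214400) from 6.78 ± 0.83 to 17.6 ± 1.51. The NAC transcription factor JUNGBRUNNEN 1 on 5B (TraesCS5B03G1024100) went from 6.10 ± 0.53 to 15.8 ± 0.94. A gene on 5B with a plastocyanin-like domain (TraesCS5B03G1063100) went from 14.7 ± 1.72 to 38.1 ± 3.83 and sits in the photosynthesis list through that domain name. The largest changes also held a second thaumatin-like protein gene on 5B (TraesCS5B03G0034800, log2 fold change 2.80). With it were a 2-alkenal reductase gene on 5D (TraesCS5D03G0704400, 2.78), of an enzyme that removes reactive carbonyls, and potassium transporter 5 on 3D (TraesCS3D03G0964400, 2.51). Adjusted p-values of the 56 lay between 0.0188 and 0.0499.

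**Figure D2:**
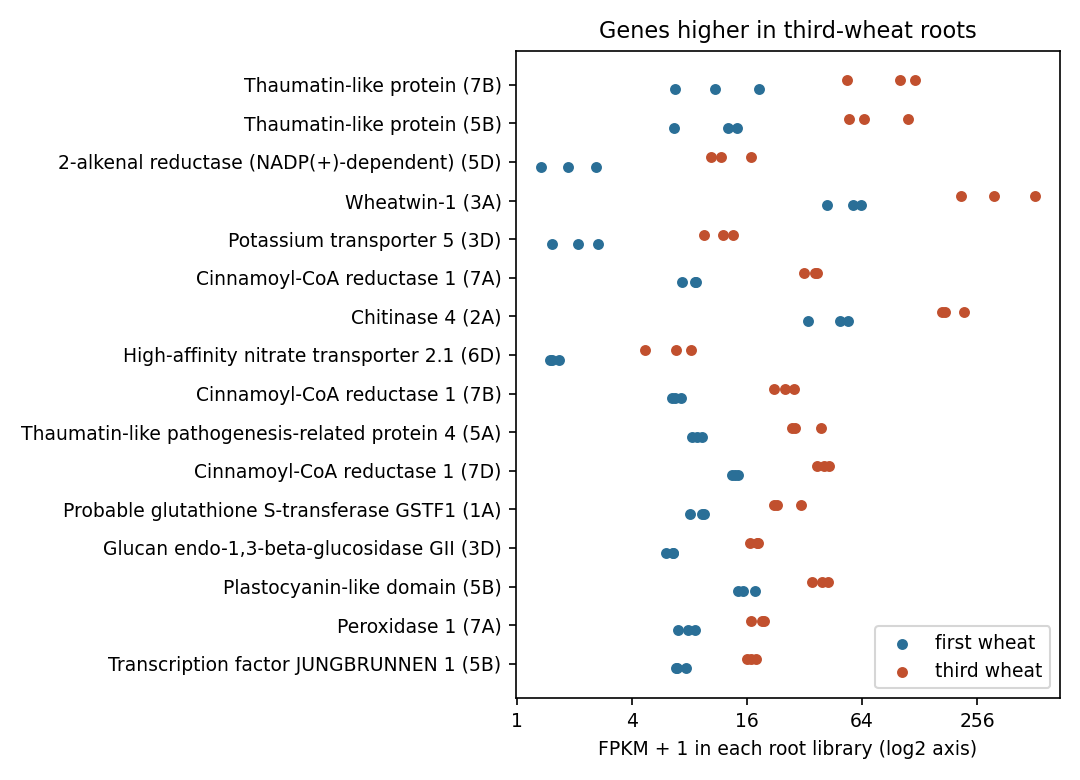
FPKM + 1 (log2 axis) of the genes the rule named in roots, apart from the SWEET entries, in each of the 6 root libraries; each point is a library, blue for first-wheat and orange for third-wheat, and the chromosome stands in brackets. For each gene the 3 third-wheat points lie above the 3 first-wheat points, as with cinnamoyl-CoA reductase 1 on 7A, whose means were 7.13 and 34.1 FPKM. This separation follows from the choice of genes: all were called as higher, and no overlap was required of those of largest change.

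Both root groups held a library that stood apart. Root library 1 of first-wheat lay at -97.1 on the first principal component of the root libraries, where the others lay between 3.4 and 37.8. Root library 1 of third-wheat had 57.7 FPKM of chlorophyll-binding transcripts against 3.74 to 9.26 in the others. Without both libraries 0 genes were called by limma (6368 at an unadjusted p under 0.05). Calls were 3 without first-wheat library 1, and 0 without first-wheat library 2 or 3 or third-wheat library 1 or 2 (4448, 4517, 5157 and 2815 at an unadjusted p under 0.05). They were 60 without third-wheat library 3. They numbered 0 without the filter (6279 at an unadjusted p under 0.05), 10 with a pseudocount of 0.1, 13 with quantile normalization, 20 with upper-quartile scaling, 172 with array weights and 522 when all 12 libraries were fitted together.

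Of the 28 lists, 15 passed camera at the preset correlation in root, 10 higher and 5 lower in third-wheat roots, and 0 passed with an estimated correlation. The root marker list (germins, nodulins, Casparian strip and root hair proteins) led, with 169 of 238 members above 0, a median log2 fold change of 0.27 and a camera adjusted p = 7.04e-09, with adjusted p = 0.257 with an estimated correlation. It had 0 members called over all genes by limma (66 at an unadjusted p under 0.05) or voom, and 33 higher and 0 lower when adjusted over the list alone. Benzoxazinoid genes, of a class of cereal defence compounds, had a median of 0.21 and a camera adjusted p = 6.16e-05, with adjusted p = 0.257 with an estimated correlation. Adjusted over the list alone, 14 members were higher and 1 lower. Leaving out first-wheat libraries 1, 2 and 3 and third-wheat libraries 1, 2 and 3 in turn gave 38, 7, 13, 0, 0 and 23 root marker members and 15, 15, 15, 12, 7 and 12 benzoxazinoid members over the list alone.

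Further root lists that were higher were phosphate starvation (median 0.13, camera adjusted p = 0.00228, list alone 0), nitrogen uptake and assimilation (0.14, 0.00472, list alone 9 higher) and pathogenesis-related (0.10, 0.00598). Glutathione S-transferase (0.11, 0.00967, list alone 21 higher and 2 lower) and phenylpropanoid and lignin (0.10, 0.0158) were higher too. Each of these 5 had an adjusted p = 0.488 with an estimated correlation. Peroxidase (0.18, 0.00875, list alone 15 higher and 2 lower) and WRKY transcription factors (0.12, 0.0347, list alone 0) were higher, with adjusted p = 0.551 and 0.627 with an estimated correlation. The photosynthesis list was higher as fixed (0.17, 0.00104, list alone 8 higher), with adjusted p = 0.488 with an estimated correlation. Without the plastocyanin-like entries its test direction turned (median 0.03, camera adjusted p = 0.636), and root library 1 of third-wheat carried the chlorophyll-binding excess given above. Without first-wheat libraries 1, 2 and 3 and third-wheat libraries 1, 2 and 3 in turn, list-alone counts were 7, 8, 10, 0, 0 and 5 for nitrogen (3 of the 10 lower), 14, 20, 5, 16, 3 and 23 for glutathione S-transferase, 9, 13, 9, 6, 2 and 11 for peroxidase and 7, 5, 5, 7, 6 and 5 for photosynthesis. WRKY had 19 without third-wheat library 1 and 0 without each other library.

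Root lists that were lower were aquaporins, which are water channels (median -0.28, camera adjusted p = 6.16e-05, list alone 3 higher and 2 lower), heat shock (-0.07, 0.00104, list alone 0) and senescence (-0.10, 0.00598, list alone 5 higher and 1 lower). Each had an adjusted p = 0.488 with an estimated correlation. Dehydrin and LEA (-0.08, 0.0164, list alone 0) and cytosolic ribosome (-0.03, 0.0347, list alone 0) were lower, with adjusted p = 0.551 and 0.789 with an estimated correlation. The aquaporin list-alone count was 5 higher and 35 lower without first-wheat library 2, 4 higher and 20 lower without third-wheat library 1, and 0 without first-wheat library 1 or 3 or third-wheat library 2 or 3. That of senescence was 0 without third-wheat library 1 or 2, and dehydrin and LEA had 1 without third-wheat library 1. JUNGBRUNNEN 1, the 1 called member of the senescence list, was higher and is known to delay senescence. Without both root libraries that stood apart 14 lists passed, 12 of them higher. Cytosolic ribosome and dehydrin and LEA then turned direction (camera adjusted p = 0.659 and 0.128), senescence did not pass (0.160) and jasmonate passed as higher (8.07e-05).

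Root lists that did not pass were cell wall expansion (median 0.10, camera adjusted p = 0.0608), fructan metabolism (0.19, 0.0700), histone and replication (-0.03, 0.0977), ethylene (-0.02, 0.243), iron and phytosiderophore (-0.02, 0.270) and starch metabolism (0.08, 0.305). Calvin cycle (0.09, 0.368), jasmonate (0.03, 0.368), monosaccharide transporter (-0.01, 0.429), invertase and sucrose synthase (0.00, 0.948), organic acid export (0.03, 0.948) and sucrose transporter (0.09, 0.948) did not pass either. Adjusted over the list alone, starch metabolism had 1 member higher, monosaccharide transporter 2 higher and the others 0. Without third-wheat library 1 jasmonate had 30, ethylene 12 and cell wall expansion 9. Fructan metabolism had 2 without first-wheat library 2 and 8 without third-wheat library 2, and iron and phytosiderophore 3 without first-wheat library 3. Starch metabolism had 0 without any 1 library, and monosaccharide transporter 0 without first-wheat library 1 or 3 or third-wheat library 1 or 2. The camera direction was opposite to the median for jasmonate, organic acid export and sucrose transporter, and the mean was opposite to the median for ethylene, jasmonate and monosaccharide transporter.

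The root marker, benzoxazinoid, aquaporin, heat shock and photosynthesis lists as fixed passed camera at the preset correlation in root without any 1 library. With all libraries and an estimated correlation 0 of them passed. Without first-wheat library 1, cytosolic ribosome (camera adjusted p = 0.962), dehydrin and LEA (0.959) and senescence (0.0849) did not pass, while cell wall expansion (0.0041) and fructan metabolism (0.00971) did. Without first-wheat library 2, WRKY (0.129), glutathione S-transferase (0.129), pathogenesis-related (0.0651), peroxidase (0.974), phenylpropanoid and lignin (0.145) and phosphate starvation (0.0651) did not pass, while fructan metabolism (0.0289) and histone and replication (0.00668) did. Without first-wheat library 3, WRKY (0.290), cytosolic ribosome (0.212), glutathione S-transferase (0.212), nitrogen (0.168) and phenylpropanoid and lignin (0.483) did not pass, while cell wall expansion (0.0165) and jasmonate (0.0108) did. Without third-wheat library 1, cytosolic ribosome (0.351), dehydrin and LEA (0.525) and nitrogen (0.134) did not pass. Without third-wheat library 2, WRKY (0.473), cytosolic ribosome (0.781) and phenylpropanoid and lignin (0.0566) did not, while cell wall expansion (0.0142), ethylene (0.0396) and fructan metabolism (0.00297) did. Without third-wheat library 3, WRKY (0.499), phenylpropanoid and lignin (0.173) and senescence (0.0668) did not, while ethylene (0.00593), histone and replication (0.0355) and jasmonate (0.0329) did.

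Third-wheat leaves differed from first-wheat leaves in 39 genes. Senescence regulator family genes on 6A and 6D (TraesCS6A03G0612000 and TraesCS6D03G0527600) fell from 52.7 ± 3.66 to 12.96 ± 5.92 FPKM (SD, n = 3) and from 26.8 ± 2.94 to 6.80 ± 2.62. A photosystem II 10 kDa polypeptide gene on 2B (TraesCS2B03G0697700) fell from 44.8 ± 6.71 to 11.96 ± 3.67 FPKM, and the subtilisin-chymotrypsin inhibitor-2A gene on 2A (TraesCS2A03G0325500) from 41.0 ± 7.09 to 10.9 ± 4.42. Gibberellin 20 oxidase 3 on 4B (TraesCS4B03G0184500), an enzyme of gibberellin synthesis, rose from 2.94 ± 0.76 to 11.8 ± 1.99. Of 47425 genes tested with limma, 10 were higher and 29 lower in third-wheat leaves, and voom called 105 higher and 215 lower.

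The lower genes named by the rule had log2 fold changes of -2.03 ± 0.26 (SE) and -1.88 ± 0.22 for the senescence regulators, -1.87 ± 0.25 for the protease inhibitor and -1.86 ± 0.22 for the photosystem II gene. Cytochrome P450 78A11 on 2B (TraesCS2B03G1517200) had -1.85 ± 0.21. The higher genes were calcium-dependent protein kinase 10 on 5B (TraesCS5B03G1055900, 1.74), a glucuronosyltransferase gene on 1D (TraesCS1D03G0143400, 1.73) and gibberellin 20 oxidase 3 (1.71). With them were the vacuolar membrane aquaporin TIP4-1 on 4B (TraesCS4B03G0908400, 1.31) and a vacuolar-processing enzyme, a protease, on 3A (TraesCS3A03G1250900, 1.10). A TIP4-1 copy on 5A (TraesCS5A03G1213000) also rose, from 186.6 ± 13.4 to 368.6 ± 17.97 FPKM. Adjusted p-values of the 39 genes lay between 0.0325 and 0.0406.

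Leaf library 1 of first-wheat stood apart on the second principal component of the leaf libraries (-74.8, others 2.3 to 28.1). Without it 148 genes were called in leaf, 69 higher and 79 lower. Without third-wheat library 1 there were 149 (17 and 132), without first-wheat library 3 there was 1, and without first-wheat library 2 or third-wheat library 2 or 3 there were 0 by limma (5349, 3945 and 4158 at an unadjusted p under 0.05). No filter gave 0 calls (7814 at an unadjusted p under 0.05), array weights gave 358 and all 12 libraries fitted together 170. Quantile normalization gave 4 higher and 22 lower.

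Of the 28 lists, 10 passed camera at the preset correlation in leaf, 5 higher and 5 lower in third-wheat leaves, and 0 passed with an estimated correlation. Cytosolic ribosome genes were higher, with 519 of 568 members above 0, a median of 0.39 and a camera adjusted p = 1.29e-31, with adjusted p = 0.536 with an estimated correlation. Limma called 0 of them over all genes or over the list alone, with 296 at an unadjusted p under 0.05, and voom called 0. Without first-wheat library 1, which stood apart, 3 were called, and 363 were higher and 8 lower over the list alone, and without each other library there were 0. Calvin cycle genes, which fix carbon dioxide, were higher (63 of 74 above 0, median 0.31, list alone 17 higher and 1 lower, camera adjusted p = 4.07e-11), with adjusted p = 0.536 with an estimated correlation. Jasmonate (median 0.23, camera adjusted p = 8.99e-05, list alone 4 higher), glutathione S-transferase (0.23, 0.000144, list alone 4 higher) and phosphate starvation (0.14, 0.00227, list alone 2 higher) were higher. They had adjusted p = 0.536, 0.564 and 0.564 with an estimated correlation. Without first-wheat libraries 1, 2 and 3 and third-wheat libraries 1, 2 and 3 in turn, list-alone counts were 22, 10, 12, 10, 9 and 19 for Calvin cycle, 25, 0, 6, 0, 0 and 5 for jasmonate, 35, 1, 1, 0, 0 and 0 for glutathione S-transferase and 4, 1, 0, 10, 0 and 0 for phosphate starvation.

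Leaf lists that were lower, beside SWEET, were photosynthesis light reactions (median -0.17, camera adjusted p = 1.09e-05, list alone 3 lower), WRKY (-0.10, 0.00509, list alone 1 lower), aquaporin (-0.20, 0.00695, list alone 2 higher and 4 lower) and senescence (-0.06, 0.0435, list alone 3 lower). They had adjusted p = 0.564, 0.536, 0.589 and 0.536 with an estimated correlation. In the photosynthesis list the 93 members that encode proteins usually carried by the chloroplast genome had a median of -1.03 and the other 183 a median of 0.01. The 2 called aquaporins, both TIP4-1, went against their list. Cytosolic ribosome, Calvin cycle, jasmonate and SWEET passed camera at the preset correlation in leaf without any 1 library. Without first-wheat library 1 the aquaporin, photosynthesis and senescence lists had adjusted p = 0.956, 0.312 and 0.187 and monosaccharide transporter passed (0.0440). Without first-wheat library 2 glutathione S-transferase had 0.102, while benzoxazinoid (0.0339) and dehydrin and LEA (0.00111) passed. WRKY and senescence had 0.0573 without first-wheat library 3. Without third-wheat library 1 senescence had 0.137 and dehydrin and LEA passed (0.0044), and without third-wheat library 3 photosynthesis had 0.145 and phosphate starvation 0.0848. The list-alone count of photosynthesis was 13 higher and 12 lower without first-wheat library 1 and 4 higher and 66 lower without third-wheat library 1 (13 called lower over all genes). It was 2 and 3 without first-wheat libraries 2 and 3 and 4 and 1 without third-wheat libraries 2 and 3. In the order first-wheat libraries 1, 2 and 3 and third-wheat libraries 1, 2 and 3, aquaporin had 5, 4, 9, 7, 3 and 2, senescence 7, 3, 3, 5, 3 and 3, and WRKY 2, 0, 0, 1, 0 and 0.

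Leaf lists that did not pass were dehydrin and LEA (median -0.10, camera adjusted p = 0.0513, list alone 1 higher and 10 lower), monosaccharide transporter (0.11, 0.169), peroxidase (0.12, 0.209, list alone 2 higher and 1 lower), organic acid export (0.08, 0.243), root marker (0.08, 0.243) and pathogenesis-related (0.09, 0.255, list alone 3 higher and 6 lower). So were iron and phytosiderophore (-0.07, 0.293, list alone 1 higher and 3 lower), cell wall expansion (-0.01, 0.320, list alone 6 higher and 9 lower), starch metabolism (0.08, 0.388, list alone 2 lower), benzoxazinoid (-0.01, 0.405), nitrogen uptake and assimilation (0.05, 0.405) and histone and replication (-0.01, 0.513). The rest were sucrose transporter (0.01, 0.513), phenylpropanoid and lignin (0.03, 0.584, list alone 1 higher), ethylene (-0.01, 0.617, list alone 8 higher and 16 lower), invertase and sucrose synthase (-0.06, 0.771, list alone 2 higher), heat shock (0.04, 0.805, list alone 3 higher and 7 lower) and fructan metabolism (0.10, 0.818, list alone 2 lower). Those without such a count had 0 when adjusted over the list alone. Without first-wheat libraries 1, 2 and 3 and third-wheat libraries 1, 2 and 3 in turn, these counts were 8, 8, 4, 16, 5 and 3 for dehydrin and LEA, 15, 14, 10, 8, 1 and 2 for cell wall expansion, 25, 16, 19, 17, 16 and 14 for ethylene and 3, 12, 4, 5, 0 and 0 for heat shock. They were 13, 0, 0, 2, 0 and 0 for pathogenesis-related, 3, 4, 3, 11, 3 and 1 for peroxidase, 2, 0, 0, 0, 1 and 0 for iron and phytosiderophore and 4, 0, 1, 0, 0 and 0 for invertase and sucrose synthase. Starch metabolism had 1, 0, 3, 2, 0 and 0, fructan metabolism 2, 0, 2, 3, 0 and 0, and phenylpropanoid and lignin 8, 0, 0, 0, 0 and 0. Of the lists at 0, nitrogen had 4 and 5 without first-wheat libraries 1 and 2, monosaccharide transporter 1 and 2 without library 1 of first-wheat and of third-wheat, and organic acid export 1 and 1. Benzoxazinoid had 1 without first-wheat library 2 or third-wheat library 3, and without third-wheat library 1 sucrose transporter had 3 and root marker 1. Over all genes 1 dehydrin and LEA member and 1 ethylene member were called lower. The camera direction was opposite to the median for sucrose transporter and for invertase and sucrose synthase, and the mean was opposite to the median for these, fructan metabolism and iron and phytosiderophore.

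**Figure D3:**
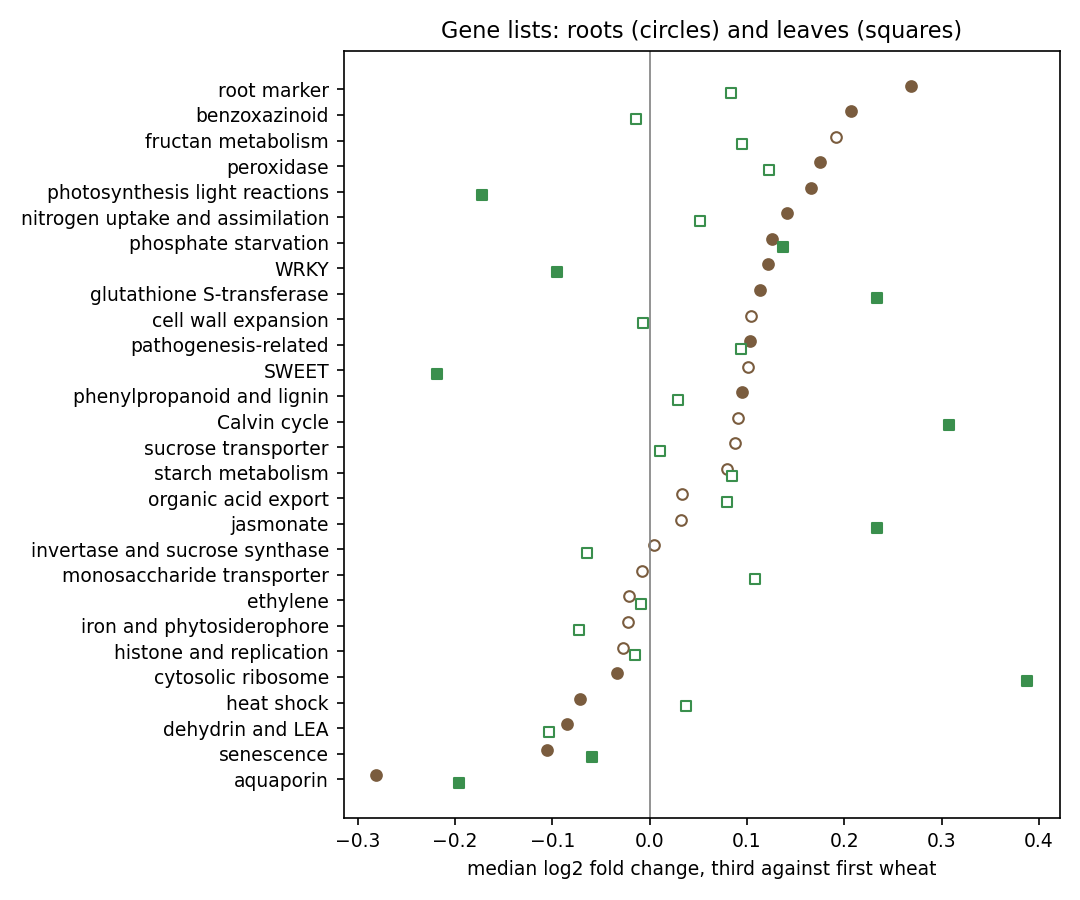
Median log2 fold change, third-wheat against first-wheat, of the 28 gene lists in roots (brown circles) and leaves (green squares); filled symbols passed camera at the preset correlation (15 in root, 10 in leaf), and 0 lists passed with an estimated correlation. The SWEET list has medians of 0.10 in root and -0.22 in leaf, and the cytosolic ribosome list has -0.03 and 0.39.

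The succession effect differed between roots and leaves for 49 genes. Chitinase 4 on 2B (TraesCS2B03G0949900) went from 50.2 ± 16.4 to 186.5 ± 24.1 FPKM (SD, n = 3) in roots and from 85.6 ± 13.7 to 55.5 ± 7.62 in leaves. Chitinase 4 on 2A (TraesCS2A03G0857500) went from 44.5 ± 10.8 to 185.9 ± 26.7 in roots and from 27.3 ± 6.11 to 22.7 ± 4.19 in leaves. Cytochrome P450 78A11 on 2B (TraesCS2B03G1517200) went from 5.12 ± 0.62 to 0.70 ± 0.25 in leaves and from 51.0 ± 4.02 to 65.5 ± 10.7 in roots. Of 61389 genes tested with limma for the difference between the organs, 48 had a more positive succession change in root and 1 in leaf, and voom called 14 and 0.

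The interaction values, root change minus leaf change on the log2 scale, were 2.20 ± 0.23 (SE, adjusted p = 0.00933) for cytochrome P450 78A11 (TraesCS2B03G1517200) and 2.53 ± 0.32 and 2.31 ± 0.29 for the chitinase 4 genes on 2B and 2A (TraesCS2B03G0949900 and TraesCS2A03G0857500). Laccase-15 on 6D (TraesCS6D03G0118900LC) had 2.35 ± 0.30 and anthranilate O-methyltransferase 3 on 3A (TraesCS3A03G1096700) had 2.40 ± 0.31. Laccase-15 had means of 0 and 0.03 FPKM in first-wheat and third-wheat leaves, so its value is in effect the root change. Other called genes, such as high-affinity nitrate transporter 2.1 on 6D (TraesCS6D03G0074700), were at 0 in every leaf library. For these genes the interaction does not show an opposite response in leaf. The 1 gene with the opposite sign, TraesCS1D03G0525500 (-1.66), has no annotation and was named after its value was seen. So was a sugar carrier protein C gene on 2A (TraesCS2A03G0431900), of the monosaccharide transporter list, with an interaction of 2.78 ± 0.44 and adjusted p = 0.0462. Of the 49 genes, 24 were among the 56 root calls and 7 among the 39 leaf calls, and the root and leaf calls shared 0 genes. With so few calls among 40161 genes tested in both organs, the 0 shared genes do not show that the organs respond differently.

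No SWEET gene passed the interaction test over all genes: limma called 0 of 42 and voom 0, and 12 had an unadjusted p under 0.05 in limma. Adjusted over the list alone, 6 list members passed, or 3 when only transporters were counted. Without leaf libraries 1, 2 and 3 of first-wheat and then of third-wheat these were 6, 0, 6, 6, 0 and 0 list members and 1, 0, 0, 2, 0 and 0 transporters. Without the root libraries in the same order they were 0, 6, 8, 6, 6 and 7 list members and 0, 2, 0, 4, 0 and 3 transporters. All 10 SWEET13 copies had an interaction above 0 (median 0.67), 5 of them with an unadjusted p under 0.05. In leaf all 10 had log2 fold changes below 0 (-0.75 to -0.31). Only 7 passed the filter in root, with log2 fold changes from -0.03 to 0.52, 6 above 0 and 1 below. The log2(FPKM + 1) scale also understates changes of copies that are low in root. These interactions therefore repeat the leaf change in large part and do not show an opposite response in root. The SWEET list had a camera adjusted p = 0.000479 for the interaction, with adjusted p = 0.468 with an estimated correlation. For transporters alone it was 0.00533, with adjusted p = 0.468 with an estimated correlation. Of the 28 lists, 9 passed camera for the interaction, 5 more positive in root and 4 in leaf, and 0 passed with an estimated correlation; this list test was chosen after the data were seen.

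Calls of the whole interaction were 18, 6 and 0 without leaf libraries 1, 2 and 3 of first-wheat and 2, 3 and 3 without those of third-wheat. They were 12, 6 and 62 without root libraries 1, 2 and 3 of first-wheat and 9, 3 and 96 without those of third-wheat. Without the 3 libraries that stood apart they were 0. At an unadjusted p under 0.05 these counts of 0 had 4695 and 6484 genes in limma. They were 28 with a pseudocount of 0.1, 3 without the filter and 102 with array weights.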

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

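The tests on reads shared between SWEET13 copies, on time of day and on chloroplast-type genes, and the comparison of root fold changes before and after quantile normalization, were chosen only after the result was seen. In all, 49 genes had succession effects that differed between roots and leaves by the interaction test. The named ones were cytochrome P450 78A11 (TraesCS2B03G1517200, log2 interaction 2.20), chitinase 4 on 2B and 2A (TraesCS2B03G0949900, 2.53, and TraesCS2A03G0857500, 2.31), laccase-15 (TraesCS6D03G0118900LC, 2.35, near 0 FPKM in leaf) and anthranilate O-methyltransferase 3 (TraesCS3A03G1096700, 2.40). Of 100 splits of the libraries, the real one included, 2 gave as many as 49 genes. A share under 0.05 was the outcome set in advance against a chance division of the libraries. It cannot exclude chance here, because splits that mix first-wheat and third-wheat libraries add any succession effect to the spread within groups. The count was also 0 without leaf library 3 of first-wheat. The highest other split gave 171 genes and exchanged first-wheat and third-wheat libraries within 1 organ. Its contrast was the sum of the root and leaf changes, which a change in 1 organ alone can also fill. For root against leaf 1 of 100 splits gave as many as the real 39337 genes, and the highest other gave 0.

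For the succession effect within an organ there are 10 splits of the 6 libraries, too few for a share under 0.05. In root the real split called 56 genes and the highest other 0 (1 of 10 as large), and in leaf 39 and 0 (1 of 10 as large). At an unadjusted p under 0.05 in limma, the real root split had 4429 genes and another split had more, 5545. In leaf the real split had 6123 and the highest other 4114. For the gene lists the real split passed 15 in root and the highest other split also 15 (2 of 10 as large), and in leaf 10 and 10 (4 of 10 as large).

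All 56 genes called in root were higher in third-wheat roots, a pattern that may be biological or technical. Leaf RNA in the third-wheat root libraries is argued against: at the highest leaf share seen, 0.256%, 0 of the 56 genes drew 10% or more of their increase from leaf transcripts, and the largest part supplied was 4.05%. Root library 1 of first-wheat stays open as a cause. Calls fell to 3 without it, with 1 of the 56 among them. They fell to 0 without first-wheat library 2 or 3 or third-wheat library 1 or 2, so the loss of calls is not particular to library 1. Without library 1 of first-wheat the median fold change of the 56 was 0.971 of its size, the outcome set in advance against it as the cause. This decides nothing, because these genes were chosen with the library in the fit. For scaling between libraries, 13 of the 56 were still called after quantile normalization, all higher. A minority still called was the outcome set in advance for scaling as the cause. Adjusted p-values had lain close to the threshold (0.0188 to 0.0499), and the number of calls does depend on scaling. The fold changes of the 56 argue against scaling as their source. Their median log2 fold change went from 1.90 (median SE 0.235) to 1.88 (0.221) and their lowest from 1.17 to 1.15. All 56 kept an unadjusted p under 0.05 in limma, while the median of all tested genes moved only from 0.021 to -0.02. An effect of succession also stays open and untested.

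SWEET13 copies had log2 fold changes below 0 in third-wheat leaves, with 0 of 10 called by limma or voom (9 at an unadjusted p under 0.05 in each), 0 SWEET members past the list-alone test without library 2 or 3 of either crop, and an exact permutation p = 0.1 for the sum; a candidate explanation is lower expression of the family under succession. Reads moved between near-identical copies are argued against, since the sum over all copies also differed, by -30.9%, with no overlap between the groups (chance gives that in 10% of such splits). Scaling is argued against, as the median log2 fold change of the tested copies was -0.56 and became -0.623 after quantile normalization. Sampling at another time of day stays open: 9 of 39 core clock genes had an unadjusted p under 0.05 in leaf (23.1% against 12.9% of other genes, Fisher exact p = 0.0877). The Fisher test treats genes as independent, though many are copies of the same clock gene measured in the same 6 libraries. Its p therefore cannot decide the question. Time of day and succession cannot be told apart here, because the labels used here give no sampling times.

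The photosynthesis list was lower in third-wheat leaves by camera at the preset correlation. That call was lost with an estimated correlation (camera adjusted p = 0.564), without leaf library 1 of first-wheat (0.312) and without leaf library 3 of third-wheat (0.145). The call may come from transcripts of chloroplast-type genes counted at nuclear copies. The 93 such members had a median log2 fold change of -1.03 and the other 183 a median of 0.013, the values that explanation needs. The summed FPKM of these 93 members was 2837 ± 516 (SD, n = 3) in first-wheat and 1137 ± 737 in third-wheat leaves. A succession effect on chloroplast transcripts themselves stays open and was not tested. Lower values were not limited to chloroplast-type genes. Genes annotated as cytochrome b, picked from the family scan, were below 0 in leaf in 7 of 7 (median -1.02, 0 called). A gene annotated as mitochondrial ribosomal protein S3 (TraesCSU03G0211000LC), named after its value was seen, went from 4.96 to 0.61 FPKM. Other mitochondrial genes were not examined as a group. A cause shared by these genes, biological or technical, was not tested.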

How the results depend on the processing

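The voom fits, the fits without libraries that stand apart and the lists without unintended entries were chosen after the data were seen. The planned edgeR quasi-likelihood test was not run, because the deposited values are FPKM and not counts. Voom on the recovered fragments was run in its place. At a depth of 14602566 to 16405500 fragments and with 3 libraries per group, simulations recovered 2% of 2-fold changes in root and 10% in leaf. Other depths and group sizes were not simulated. Where no cause is named below, the cause was not tested.

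Genes changed in root, 56 in the main analysis, were 10 with a pseudocount of 0.1, 0 without the filter (6279 at an unadjusted p under 0.05 among 105593 tested), 13 with quantile normalization, 20 with upper-quartile scaling, 172 with array weights, 522 in 1 fit of 12 libraries and 0 without the 2 libraries that stood apart (6368 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 60. Genes changed in leaf, 39, were 0 without the filter (7814 at an unadjusted p under 0.05 among 97856 tested), 358 with array weights, 170 in 1 fit of 12 libraries and 320 with voom, and 0 to 149 without 1 library. The interaction, 49, was 28 with a pseudocount of 0.1, 3 without the filter, 102 with array weights, 14 with voom, 0 without the 3 libraries that stood apart, and 0 to 96 without 1 library. Root against leaf, 39337, was 22100 with a log2 fold change of at least 1, by construction, and 37388 to 38986 without 1 library. All gene lists that passed for succession were lost with an estimated correlation (0 in root, 0 in leaf), and fry gave 1 in root (benzoxazinoid, adjusted p = 0.0477) and 0 in leaf. Without 1 library 11 to 15 lists passed in root and 8 to 11 in leaf. The SWEET sum differed by 38.8 to 97.9 FPKM in root and -496.8 to -345.7 in leaf without 1 library.

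The labels used here do not say whether the sample numbers of the titles pair the samples. Number 3 joins first-wheat libraries named 3 to third-wheat libraries named 4. Correlations of deviations of same-numbered libraries were -0.133, 0.021 and -0.027 between the root groups and -0.042, -0.044 and 0.073 between the leaf groups. Between leaf and root they were 0.329, 0.197 and 0.020 in first-wheat and -0.009, 0.011 and -0.057 in third-wheat samples. Leaf and root samples of the same number may therefore be related in first-wheat. The fits on 12 libraries treated leaf and root samples as independent, and a pairing of them within a crop was not fitted. With the number as a block, calls were 2 in root, 74 in leaf, 15 for the interaction and 39000 for root against leaf, and lists 16 in root and 11 in leaf, where cell wall expansion (root, 0.0378) and dehydrin and LEA (leaf, 0.0182) passed. Of the named genes 16 in root, 2 in leaf and 2 of the interaction lost their call under the block, and no other named gene or list changed its call. With a pseudocount of 0.1 dehydrin and LEA also passed in leaf (0.0460).

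Directions turned in few places. SWEET13 on 6B (TraesCS6B03G1183800) in root ranged from -0.118 to 0.338 without 1 library. Without the 2 root libraries that stood apart these root lists turned: cytosolic ribosome (adjusted p = 0.659), dehydrin and LEA (0.128), ethylene (0.0576), invertase and sucrose synthase (0.675), jasmonate (8.07e-05, higher) and organic acid export (0.413). Photosynthesis in root turned without its unintended entries (0.636), and with fry monosaccharide transporter (0.954), organic acid export (0.899) and sucrose transporter (0.937) did. Lists that did not pass with all libraries and turned without 1 library had adjusted p ranges, in root, of 0.00593 to 0.959 (ethylene), 0.473 to 0.959 (invertase and sucrose synthase), 0.0108 to 0.434 (jasmonate), 0.325 to 0.777 (monosaccharide transporter), 0.0591 to 0.901 (organic acid export) and 0.757 to 0.950 (sucrose transporter), and in leaf of 0.0339 to 0.974 (benzoxazinoid), 0.00111 to 0.837 (dehydrin and LEA), 0.858 to 0.974 (fructan metabolism), 0.553 to 0.981 (heat shock), 0.538 to 0.966 (invertase and sucrose synthase), 0.0747 to 0.884 (pathogenesis-related) and 0.0747 to 0.895 (phenylpropanoid and lignin). Over all alternatives, named genes gave 453 values on the same side of the threshold, 205 weaker ones and 2 with another sign, and lists 509, 82 weaker, 20 stronger and 33 with another sign. The 453 include all 16 root-against-leaf genes in every alternative, and SWEET entries that had no call to lose. All weaker values of named genes fell on the succession and interaction genes. Of 19 root genes, 2 were weaker with voom and 16 without first-wheat library 2 or 3. Of 14 leaf genes, all stayed on the same side with voom and 11 were weaker without third-wheat library 2 or 3. Of 5 interaction genes, all stayed with quantile normalization and all were weaker without first-wheat leaf library 3.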

Other observations

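A scan of annotation families, chosen after the data were seen, described gene groups by their annotation text. It took 2540 families in root and 2182 in leaf, and camera at the preset correlation passed 246 and 290. With an estimated correlation 0 passed, with adjusted p = 0.998 in root and 0.974 in leaf for the families named here. In roots, aromatic-L-amino-acid decarboxylases, which make tryptamine and tyramine, had log2 fold changes above 0 in 18 of 18 genes (median 1.23, 2 called). Homeobox-leucine zipper HOX26 genes were above 0 in 5 of 5 (median 1.57, 2 called) and germin-like protein 8-11 in 35 of 37 (median 0.54, 0 called). Aquaporin PIP1-5 genes, of the plasma membrane, were below 0 in 9 of 9 (median -1.003, 0 called), and senescence-specific cysteine protease SAG39 genes in 55 of 62 (median -0.48, 0 called).

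In leaves, Rubisco small chain genes annotated as PWS4.3 were above 0 in 7 of 7 (median 0.87, 0 called), elongation factor 1-alpha genes in 18 of 21 (median 0.39, 0 called) and the jasmonate repressor TIFY 11e in 12 of 12 (median 1.06, 0 called). Zinc finger CO3 genes were below 0 in 6 of 6 (median -0.91, 0 called) and galactinol synthase 2, of raffinose synthesis, in 8 of 8 (median -0.83, 0 called). The subtilisin-chymotrypsin inhibitor-2B genes were below 0 in 5 of 5 (median -1.65, 2 called).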
